A study of Mus musculus with 6 samples.

How the data were processed

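Total RNA from mouse ovarian surface epithelial (MOSE) cells was sequenced in 6 libraries, 3 from the line MOSE-NEO and 3 from the line MOSE-PAX8, which overexpresses the transcription factor PAX8. Both lines were kept under G418, per the labels' protocols, and the labels name 1 cell line per group. Groups and replicate numbers were taken from the sample titles.

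The deposited values are raw read counts per gene, 1 table per library, with 25006 Ensembl gene identifiers and no rows for unassigned reads. Per the submitters' processing notes, the tools were cutadapt 1.13, STAR and DESeq2 (no version given), HTSeq 0.6.1p1 and the mm10 build. The gene annotation, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. Genes with near-identical copies are therefore uncertain: Gapdh, which has many pseudogene copies, had only 2.67 to 9.54 CPM (counts scaled to the total of the library) over the libraries, and ribosomal protein genes such as Rps6 (0.671 CPM in MOSE-NEO) and Rpl19 (1.32 CPM) were as low. Counts of overlapping and antisense genes are uncertain without a stated strand. Genes of the mitochondrial genome had 0 counts in every library, so the mitochondrial share was not used.

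Gene symbols, coordinates, transcript lengths and GC content were taken from GENCODE release M21 on the same build, and 24991 of the identifiers matched it. The other 15 kept their identifiers. Coordinates are mm10, counted from 1.

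Library totals ranged from 23623762 to 36367825 counts. A gene with 0 counts in a library was given the level of 3 counts as its upper limit, which lies between 0.0825 and 0.127 CPM of the library total, and such limits cover counting error only. For a gene at 0 in all libraries of a group, the fold is a lower bound against 3 counts over the whole group. For a gene with 1 to 3 counts in a group, the ratio is given with an exact counting interval at a level of 95%.

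The comparison was MOSE-PAX8 against MOSE-NEO, fitted on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05, and a second count required an absolute log2 fold change of at least 1. CPM values in the text use the TMM factors and are means ± SD over 3 libraries, and positive log2 fold changes are higher in MOSE-PAX8. Log2 fold changes carry a standard error (SE) worked back from the estimate and its test statistic. For a gene with 1 to 3 counts in a group this SE can understate the counting error, and the counting interval is used in its place. Nothing in the labels says that the 3 libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

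Before the data were examined, 26 gene lists were fixed: PAX family, PAX8 targets, Mullerian epithelium, ovarian surface and mesothelium, epithelial, mesenchymal, extracellular matrix, matrix proteases and inhibitors, adhesion receptors, G2/M and FOXM1, DNA replication, p53 targets, interferon response, inflammatory signalling, TGF-beta and BMP, Wnt, growth factors and receptors, actin cytoskeleton and SRF, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid response, ribosomal proteins, and markers of leukocytes, endothelium, granulosa and theca cells, and stromal fibroblasts. The 24 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists.

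The rule for named genes was fixed at the same time. It took Pax8 and any other Pax gene with at least 10 counts in total; the 10 called genes with the largest log2 fold change in each direction, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups; and from each list up to 2 called members per direction with the smallest adjusted p, or, if none was called, the 2 most abundant. Symbols of the Gm number, Rik and -ps kinds were passed over for the next gene, whatever the annotated biotype. Other members of the fixed lists are named as examples of their list, and genes outside both sets were chosen after their values were seen. Some genes that the rule selects are not reported here.

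Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, camera with an estimated correlation, fry, and a test against a fold of 1.5. Further alternatives, on chromosome-wide shifts and on 2 libraries with more lincRNA, were added after seeing the data.

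The fit was tested on simulated counts for 12200 genes with the means and library sizes of this comparison. It recovered 56.7% of 67 genes changed 1.5-fold, 83.1% of 65 changed 2-fold and 100% of 64 changed 4-fold. The calls included 17 unchanged genes, or 9.83% of all calls, above the nominal 5%, and 0 genes were called in counts with no change. The simulated changes covered a much smaller share of genes than the 33.9% called in the real comparison, so these rates need not hold there. With 1 list shifted, camera called 2 lists, the shifted list among them, and 0 lists with none shifted. The simulated genes were drawn independently of each other. These list counts therefore cannot show how camera behaves where the members of a list are correlated. A shift of 0.4 was added to the fitted log2 fold changes of the genes of 1 chromosome, not to the counts. The local chromosome median returned 0.388, which checks that median only and not the fit. Figures were drawn with matplotlib 3.10.9.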

Results

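Gene expression was measured by RNA sequencing in 2 stable lines of mouse ovarian surface epithelial (MOSE) cells, the epithelium that covers the ovary. MOSE-PAX8 overexpresses PAX8, a paired-box transcription factor that acts in thyroid, kidney and Mullerian duct development, and MOSE-NEO is the reference line, with 3 libraries each. MOSE-NEO libraries 1 to 3 held 32057173, 23623762 and 30763138 counts, and MOSE-PAX8 libraries 1 to 3 held 36367825, 30621528 and 31785984. Between 14397 and 15578 genes were detected per library. Log2 CPM correlated at 0.989 or more across genes within a line and at 0.946 or less between lines, where genes are not independent replicates. The first principal component carried 83.8% of the variance and separated the lines. Counts of libraries from the same line differed by at least 13.3 times the sampling variance, so each was kept as a separate sample. One library of each line, MOSE-NEO 1 and MOSE-PAX8 2, had 0.317% and 0.33% of its counts in lincRNA genes, against 0.146% to 0.195% in the other libraries.

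Pax8 transcripts were nearly absent from MOSE-NEO and abundant in MOSE-PAX8. The gene (chromosome 2, 24420560 to 24475599) had 0, 1 and 1 counts in the MOSE-NEO libraries and 2570, 2973 and 3544 in the MOSE-PAX8 libraries. The level in MOSE-PAX8 was 91 ± 19.6 CPM (SD, n = 3), above that of 76.5% of the tested genes. The ratio between lines was 3810, with a counting interval of 1050 to 31500 that reflects the few counts in MOSE-NEO. The log2 fold change was 11.68 (edgeR adjusted p = 3.89e-07), or 11.08 without MOSE-NEO replicate 1. Counts per gene do not separate transcripts of an introduced Pax8 from those of the endogenous gene. Pax6 was the other Pax gene with at least 10 counts, 18 in MOSE-NEO and 8 in MOSE-PAX8, too few for the test, so Pax8 was the only one of 9 members of the PAX family tested.

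The next comparison asked which genes differed between the line that overexpresses PAX8 and its reference. The genes with the largest rise included Ankrd1, a stretch-responsive ankyrin repeat protein, at 188 ± 78 CPM in MOSE-PAX8 (SD, n = 3) against a single count in all MOSE-NEO libraries, and Cdh6, a cadherin of kidney and Mullerian epithelia, which was at least 902-fold higher with 0 counts in MOSE-NEO. Blnk, an adaptor protein of B cell signalling, reached 132 ± 27.1 CPM and Glis3, a zinc finger transcription factor, 58.5 ± 8.72 CPM, each from 2 counts in MOSE-NEO. Aldh1a2, which makes retinoic acid, fell from 42 ± 9.57 CPM to 1 count in the 3 MOSE-PAX8 libraries together. Fam208a, which encodes the HUSH silencing complex subunit TASOR, fell 109-fold from 27.4 ± 4.89 to 0.246 ± 0.135 CPM (log2 fold change -6.77 ± 0.28 SE, edgeR adjusted p = 1.7e-06).

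Among the other genes of the largest rise, Tspan18, Ptn and Kcnj16 had 0 counts in MOSE-NEO and were at least 436-fold, 341-fold and 326-fold higher in MOSE-PAX8. Ptn encodes the growth factor pleiotrophin and Kcnj16 a potassium channel. Xist, the non-coding RNA that silences an X chromosome, had 7 counts in MOSE-NEO and 52815 in MOSE-PAX8. Sprr2g, annotated as a polymorphic pseudogene with close paralogs and therefore uncertain, rose from 2 counts to 62.6 ± 19.1 CPM. Among the other genes of the largest fall, H2-DMa, a chaperone of MHC class II peptide loading, was 22.7-fold lower, the sorting receptor gene Sorcs1 20.8-fold lower and the surface glycoprotein gene Thy1 18.7-fold lower. Hpcal1, Etfbkmt, Hr, Fam213a and Acot11 were 16.5-fold, 11.4-fold, 9.32-fold, 8.36-fold and 6.68-fold lower. The rule that chose these genes required a pass in the edgeR test and no overlap between the libraries of the lines. Their adjusted p ran from 3.03e-07 (Glis3) to 0.000144 (Acot11).

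**Figure D1:**
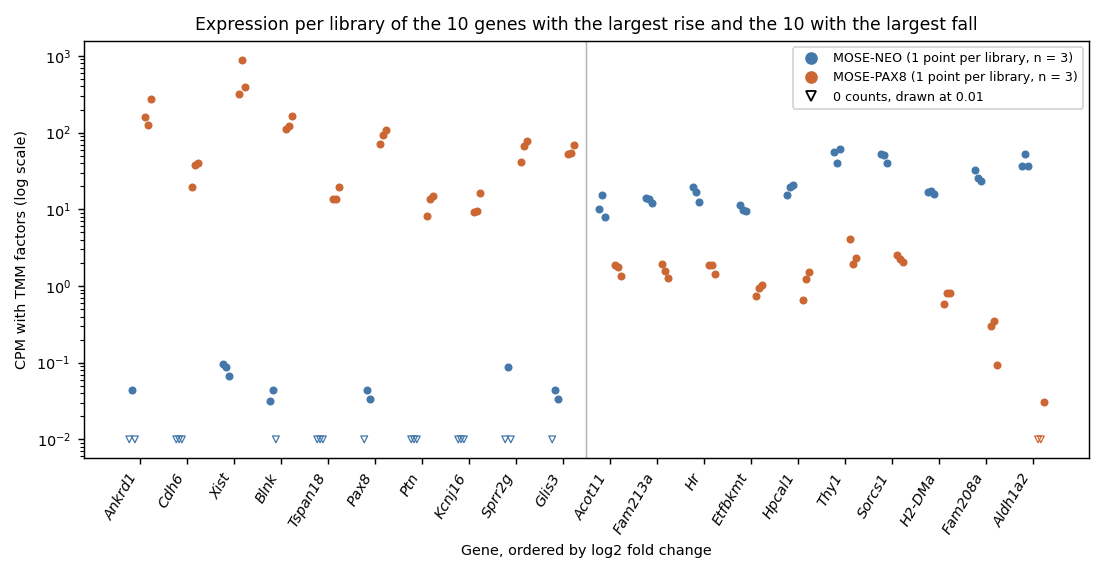
CPM with TMM factors on a log scale for the 10 genes with the largest rise and the 10 with the largest fall, 1 point per library and 3 libraries per line, with triangles at 0.01 for 0 counts. By the rule that chose the genes, MOSE-PAX8 libraries lie above MOSE-NEO libraries for those on the left, such as Pax8 at 70.3 to 109 CPM, and below them for those on the right.

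Of 12313 genes tested, 4178 (33.9%) were called, 2199 higher and 1979 lower in MOSE-PAX8. Of these, 1135 changed at least 2-fold, 747 higher and 388 lower, and among changes of at least 8-fold 281 were higher and 50 lower. An unadjusted p below 0.05 was reached by 5290 genes. In 47.6% of tested genes the 3 libraries of a line lay wholly on one side of the other 3, against 10% by chance. Most called changes were small, with a median absolute log2 fold change of 0.59. The count of lower genes was 1314 without MOSE-PAX8 replicate 3, and a test against a fold of 1.5 called 700 higher and 370 lower genes.

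Changes were also uneven along the genome. The 393 tested genes of chromosome 14 had a median log2 fold change of -0.43, with 88.3% of them below 0, 251 called lower and 25 higher. Chromosomes 7, 12 and 19 had medians of 0.27, 0.19 and 0.17, and chromosome 3 changed from -0.53 between 96.61 and 104 Mb to 0.51 between 142.5 and 159.9 Mb. The chromosome 14 median was -0.45, -0.43 and -0.4 in the MOSE-PAX8 libraries 1 to 3, each set against the mean of MOSE-NEO. Fam208a, Hr, Fam213a, Nid2, Bmp4, Fgf9 and Rps24 lie on chromosome 14. Without the genes of chromosomes 3, 7, 12, 14 and 19, chosen after seeing the data, 2665 genes were called, 1418 higher and 1247 lower.

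**Figure D2:**
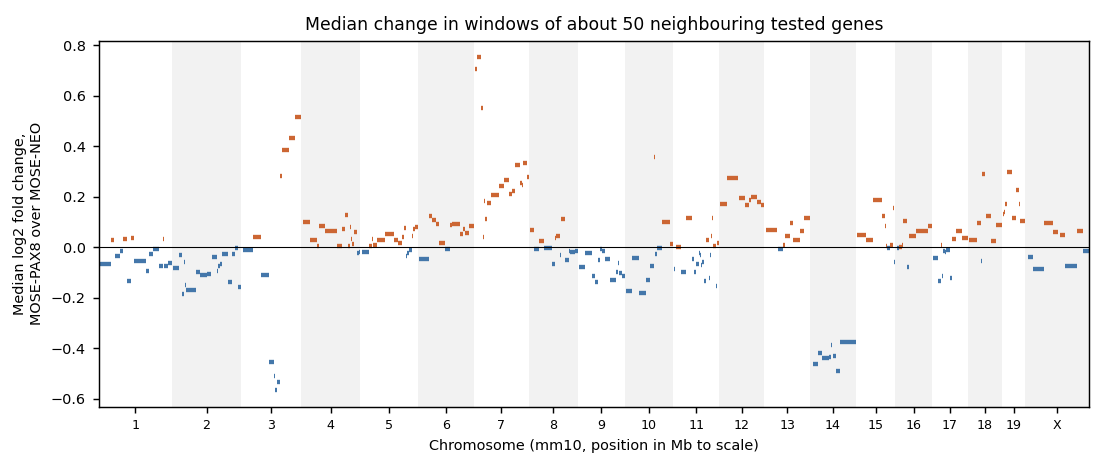
Median log2 fold change of MOSE-PAX8 over MOSE-NEO in windows of about 50 neighbouring tested genes, drawn along each chromosome at its mm10 position in Mb. All 8 windows of chromosome 14 lie below 0, the start of chromosome 7 reaches 0.75, and chromosome 3 changes sign.

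The gene lists addressed which functions changed. Genes of the actin cytoskeleton and of SRF, the serum response factor that controls them, were higher in MOSE-PAX8: 18 of 20 tested members rose and 0 fell. Tagln, a smooth muscle actin-binding protein, rose 100-fold to 283 ± 102 CPM, and Acta2, smooth muscle actin, 44.9-fold to 549 ± 164 CPM (SD, n = 3). Actb rose 1.39-fold, Myh9 1.71-fold and Cnn2 4.21-fold, and Actg1 and Tpm4 did not pass, with log2 fold changes of 0.05 ± 0.12 and 0.16 ± 0.1 (SE). Actg1 had only 17 CPM in MOSE-NEO against 1790 CPM for Actb, and whether the treatment of reads with several alignments lowered it was not tested. Camera gave the list an adjusted p of 9.08e-16, and adjusted p = 0.205 with an estimated correlation. The same 18 members passed when adjusted over the list alone.

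Adhesion receptors and mesenchymal genes were higher as lists, with exceptions. Of 22 adhesion receptors 10 rose and 3 fell, or 11 and 3 adjusted over the list alone. Besides Cdh6, the collagen receptor Itga1 rose 56.8-fold, the immunoglobulin-type receptor Alcam 20.1-fold and the hyaluronan receptor Cd44 from 0.153 to 21 CPM, while Itga7, a laminin receptor, and Mcam were 1.86-fold and 1.31-fold lower. Of 16 mesenchymal genes 8 rose and 2 fell, the same adjusted over the list alone. Fibronectin (Fn1) rose 4.19-fold, N-cadherin (Cdh2) 2.55-fold and the repressor Snai2 4.07-fold, while Sparc and S100a4 were 1.61-fold and 1.98-fold lower; Acta2 and Tagln stand in this list too, and S100a4 lies in the lowered part of chromosome 3. With the local chromosome median removed S100a4 and Mcam lost their calls (edgeR adjusted p = 0.131, range 2.81e-05 to 0.131, and 0.0871, range 0.00172 to 0.0871), and Mcam also with both lincRNA-rich libraries left out (0.0598). The camera adjusted p was 1.1e-06 for adhesion receptors and 4.82e-05 for mesenchymal genes, and adjusted p = 0.205 for each with an estimated correlation.

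Growth factor genes and their receptors moved in both directions. Of 28 tested, 12 rose and 7 fell, or 13 and 8 adjusted over the list alone. The receptors Fgfr1 and Fgfr2 rose 4.47-fold and 3.62-fold, the EGF receptor ligand Tgfa 6.67-fold and the IGF-binding protein Igfbp2 56.6-fold, while the fibroblast growth factors Fgf2 and Fgf9 were 1.82-fold and 2.07-fold lower. Camera called the list higher (adjusted p = 0.01), with adjusted p = 0.205 with an estimated correlation. The estimate was -0.02, below the preset 0.01, so correlation among the members does not account for this lost call. With limma-voom the call ended (camera adjusted p = 0.192). Over all alternatives the adjusted p ranged from 0.000325, given by fry, which does not compare a list with other genes, to 0.205 with camera.

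DNA replication genes were slightly higher. Of 30 members 18 rose and 0 fell, or 22 and 0 adjusted over the list alone, with a list median of 0.32 on the log2 scale. The flap endonuclease Fen1 rose 1.6-fold, the chromatin assembly factor subunit Chaf1a 1.51-fold and the helicase subunit Mcm2 1.29-fold. Camera gave an adjusted p of 0.00227, and adjusted p = 0.739 with an estimated correlation, which was 0.564. In the G2/M and FOXM1 list 9 of 28 members rose and 1 fell (11 and 1 adjusted over the list alone), among them Foxm1 (1.31-fold higher) and Ccnb2 (1.31-fold lower), and the list was not called (camera adjusted p = 0.132). Foxm1 lost its call without MOSE-PAX8 replicate 3 (edgeR adjusted p = 0.0506) and with both lincRNA-rich libraries left out (0.0564), and Ccnb2 without MOSE-NEO replicate 2 (0.0505) or MOSE-PAX8 replicate 3 (0.0652).

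Target genes of p53, the stress-response transcription factor, were lower. Of 21 members 15 fell and 2 rose, the same adjusted over the list alone, and the list median was -0.42 on the log2 scale. The cell cycle inhibitor gene Cdkn1a fell 4.29-fold from 156 ± 15.2 to 36.5 ± 1.78 CPM (SD, n = 3), Perp, a desmosomal apoptosis effector, 2.5-fold, and Mdm2, the ubiquitin ligase of p53, 1.47-fold. Gdf15, a stress-induced cytokine, rose 10.9-fold and the kinase gene Plk2 1.66-fold. Trp53 itself had 155 ± 14 CPM in MOSE-NEO and 175 ± 5.81 CPM in MOSE-PAX8 (edgeR adjusted p = 0.155). Camera gave the list an adjusted p of 1.17e-05, and adjusted p = 0.314 with an estimated correlation.

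Markers of the ovarian surface and mesothelium were lower as a list: 9 of 17 fell and 1 rose, or 11 and 2 adjusted over the list alone. Besides Aldh1a2, the sialomucin podocalyxin (Podxl) fell 2.29-fold from 3310 ± 225 to 1450 ± 33.3 CPM (SD, n = 3) and the transcription factor Wt1 1.63-fold, while Nr2f2, a nuclear receptor, rose 1.89-fold. Mesothelin (Msln) did not pass, with 271 and 252 CPM. Camera gave an adjusted p of 4.82e-05, and adjusted p = 0.314 with an estimated correlation. Of 8 tested genes of the Mullerian epithelium 5 fell and 2 rose, the same adjusted over the list alone: the oestrogen receptor Esr1 was 10.6-fold and the homeobox gene Hoxa10 4.94-fold lower, and Fgfr2 and Wnt4 rose 3.62-fold and 7.63-fold. Camera called this list lower (adjusted p = 0.0156), with adjusted p = 0.214 with an estimated correlation. The estimate was -0.097, below the preset 0.01, so correlation among the members does not account for this lost call. The call also ended with DESeq2 (adjusted p = 0.0678, list median -0.001), limma-voom (0.118), no low-count filter (0.125, where the list median was 0.59) and without MOSE-PAX8 replicate 1 (0.0679), over a range of 0.000179 to 0.214.

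**Figure D3:**
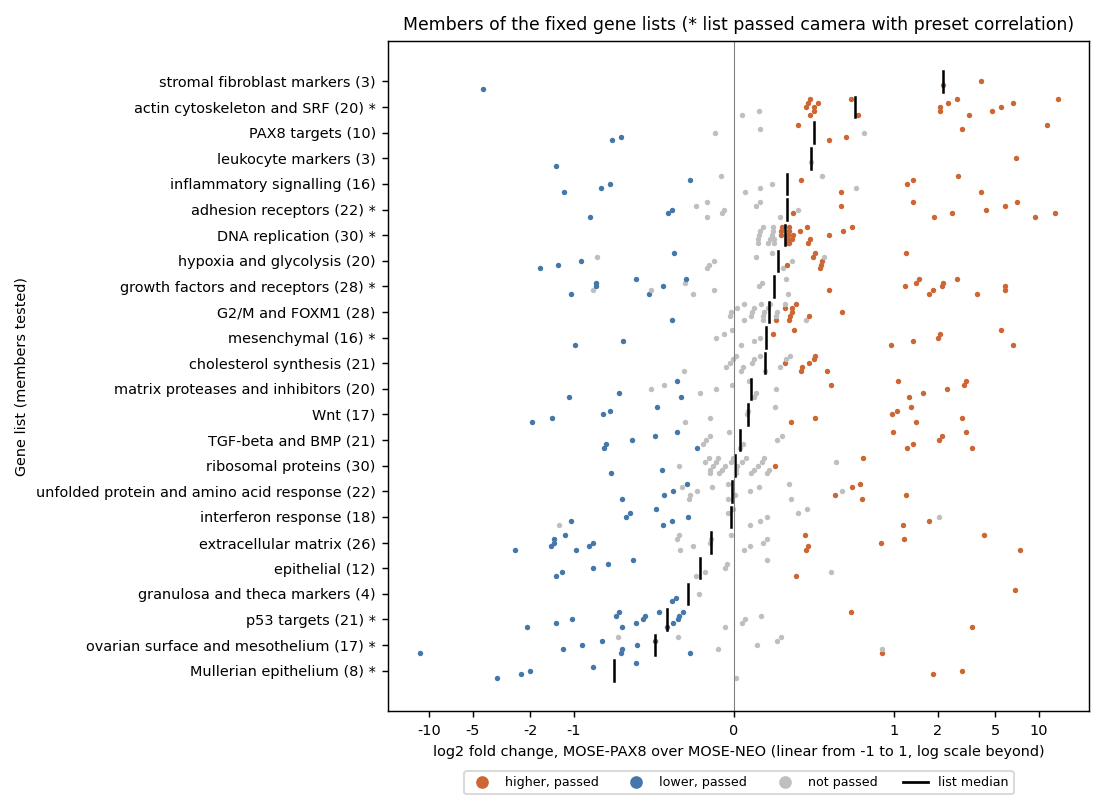
Log2 fold change of MOSE-PAX8 over MOSE-NEO for each tested member of the 24 tested lists, linear from -1 to 1 and on a log scale beyond, with a bar at each list median. The actin list has 18 members higher and the p53 target list 15 lower, and the ribosomal list stays close to 0.

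Some lists had members that rose and members that fell and were not called by camera. Of 26 extracellular matrix genes 7 rose and 8 fell (7 and 9 adjusted over the list alone): tenascin C (Tnc) rose 179-fold to 651 ± 168 CPM and Col12a1 18.5-fold, while Col1a2 and Nid2 were 2.58-fold and 5.93-fold lower (SD, n = 3). The median of this list was -0.15 and its mean 0.13 (camera adjusted p = 0.994). Among 20 matrix proteases and inhibitors 7 rose, such as Adamts4 (5.04-fold), and 4 fell, such as Adamts12 (2.1-fold) and Timp3 (1.65-fold), or 7 and 5 adjusted over the list alone (camera adjusted p = 0.214). Among 10 PAX8 targets fixed beforehand 5 rose, Kcnj16 and Wnt4 among them, and 2 fell, Wt1 and Gata3, the same adjusted over the list alone (camera adjusted p = 0.214). In the epithelial list 1 of 12 rose (Dsp, 1.31-fold) and 5 fell, with Krt7 1.84-fold and Tjp3 2.31-fold lower, the same adjusted over the list alone (camera adjusted p = 0.132). Dsp lost its call without each of 5 libraries in turn (edgeR adjusted p from 0.0627 without MOSE-PAX8 replicate 1 to 0.11 without MOSE-NEO replicate 3 or MOSE-PAX8 replicate 2; 0.0701 without MOSE-NEO replicate 1 and 0.079 without MOSE-PAX8 replicate 3), and with both lincRNA-rich libraries left out (0.134).

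Signalling lists also moved both ways. Of 21 TGF-beta and BMP genes 7 rose, such as Tgfb2 (4.11-fold), and 6 fell, such as Bmp4 (1.74-fold) and Tgfbr3 (1.76-fold), or 8 and 6 adjusted over the list alone (camera adjusted p = 0.269). Of 17 Wnt genes 7 rose, Fzd8 2.69-fold, and 5 fell, Wnt5b 2.67-fold and Wnt9a 1.76-fold, the same adjusted over the list alone (camera adjusted p = 0.994). Of 16 inflammatory genes 6 rose, with the chemokine Cxcl12 15.9-fold and Birc3 6.89-fold higher, and 4 fell, with Ccl2 2.25-fold and Lif 1.78-fold lower, the same adjusted over the list alone (camera adjusted p = 0.472). The log2 fold change of Cxcl12 was 3.99, and 4.8 without MOSE-NEO replicate 2. Interferon response genes split into 2 that rose, Cxcl10 and Ifit3 at 1.59 and 0.68 CPM in MOSE-PAX8, and 7 that fell, such as Isg15 (2.06-fold), of 18 tested, or 3 and 7 adjusted over the list alone. The median and mean of this list were -0.02 and 0.05 (camera adjusted p = 0.519). With 1 library left out in turn, the median over the members then tested ranged from -0.134 to 0.047. Ifit3 lost its call in several settings, DESeq2 among them (adjusted p = 0.133, range 0.0137 to 0.133), and without MOSE-NEO replicate 1 or 2 or MOSE-PAX8 replicate 1 or 3 (0.0749, 0.0833, 0.0799 and 0.0808). The same held with the replicate number as a block (0.0561) and with both lincRNA-rich libraries left out (0.0702).

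Metabolic lists were not called. Of 21 cholesterol synthesis genes 7 rose and 0 fell, such as Sqle (1.49-fold) and Dhcr7 (1.41-fold, on chromosome 7), the same adjusted over the list alone (camera adjusted p = 0.207). Dhcr7 lost its call with the local chromosome median removed (edgeR adjusted p = 0.0966, range 4.37e-05 to 0.0966), as did Ldha (0.0644, range 0.000299 to 0.0644). Hypoxia and glycolysis genes included 7 of 20 that rose, Ldha (on chromosome 7) and Pfkl each 1.46-fold, and 4 that fell, such as Pdk1 (3.25-fold) and P4ha2 (1.94-fold), the same adjusted over the list alone; the median was 0.27 while the set test pointed down (camera adjusted p = 0.994). In the unfolded protein and amino acid response list 5 of 22 rose, with the serine synthesis gene Psat1 2.31-fold and Shmt2 1.72-fold higher, and 4 fell, with Ddit4 1.62-fold and Sesn2 1.3-fold lower, or 6 and 5 adjusted over the list alone; median and mean were -0.01 and 0.12 (camera adjusted p = 0.994). Of 30 ribosomal protein genes 2 rose and 2 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.994). The direction of this list turned in several settings, upper-quartile factors among them but not RLE factors, while its median stayed near 0. Called genes included Rps15 (1.19-fold higher), Rps24 (1.36-fold lower) and Rps27 (1.7-fold lower). Rps15 kept its call only without MOSE-PAX8 replicate 2 among the libraries left out in turn (edgeR adjusted p up to 0.152, without MOSE-PAX8 replicate 3), and lost it with no low-count filter (0.0574) and the replicate number as a block (0.0621). With the local chromosome median removed Rps15, Rps24 and Rps27 lost their calls (edgeR adjusted p = 0.296, 0.685 and 0.446), Rps15 with its direction turned to -0.124, and Rps27 also with both lincRNA-rich libraries left out (0.0546).

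Of the markers of other cell types that a culture from the ovary could hold, few had enough counts for the test, and these moved apart. The leukocyte gene Ptprc had 1 count in MOSE-NEO and 1.95 ± 0.632 CPM in MOSE-PAX8, while Csf1r fell 2.52-fold (SD, n = 3); of 3 tested, 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.541). Granulosa and theca markers included Foxl2, with 1 count in MOSE-NEO and 1.81 ± 0.513 CPM in MOSE-PAX8, and Inha and Star, which were 1.31-fold and 1.28-fold lower. Inha and Star were not scarce, with 30.3 and 476 CPM in MOSE-NEO and 23.2 and 371 CPM in MOSE-PAX8. Of 4 tested 1 rose and 2 fell, or 1 and 3 adjusted over the list alone. The list had a median of -0.29 and a mean of 1.47 (camera adjusted p = 0.994). Star lost its call without each library in turn except MOSE-NEO replicate 1 (edgeR adjusted p from 0.0633 to 0.0896), and Inha with the local chromosome median removed (0.0525, range 0.00418 to 0.0525). Of 3 stromal fibroblast markers Cxcl12 rose 15.9-fold and Des 4.55-fold while Thy1 was lower, the same adjusted over the list alone, and the median of 2.19 and the set test differed in direction (camera adjusted p = 0.994). Without MOSE-NEO replicate 2 this median was 0.23, with the set test turned, and Cxcl12 had a log2 fold change of 4.8 in place of 3.99. The median was 0.457, 0.299 and 0.299 without MOSE-PAX8 replicate 1, 2 or 3. Des, the middle of the 3 markers, stayed at 1.874 to 2.421 on the log2 scale with each library left out. The lower medians therefore reflect further list members that passed the low-count filter in the smaller sets, not a change in these 3. Both endothelial markers with enough counts, Eng and Esam, did not pass (edgeR adjusted p = 0.176 and 0.758).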

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

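The settings on chromosome shifts and lincRNA were chosen after the results were seen. Of the 94 named genes that were called, Pax8 included, 79 stayed called in the same direction in every setting that tested them. Most named genes were picked for a large change or a small adjusted p, so this share does not extend to all called genes. Each of the 8 called lists lost its call in at least 1 setting. Settings moved the counts as follows. Camera with an estimated correlation called 0 lists and fry, which does not compare a list with other genes, called 13. A test against a fold of 1.5 called 1070 genes, 700 higher and 370 lower, by its construction fewer. Without the genes of chromosomes 3, 7, 12, 14 and 19, 2665 were called, 1418 higher and 1247 lower, from 9528 tested. Leaving out 1 library gave 2859 to 3908 called genes, 1545 to 2065 higher and 1314 (without MOSE-PAX8 replicate 3) to 1843 lower, 1013 to 1186 changed at least 2-fold, 8 to 10 lists and a Pax8 change of 11.081 to 12.136. DESeq2 called 4164 genes, 3879 of them shared with edgeR. With the local chromosome median removed 3286 were called, 2896 of them shared, and 10 named genes lost their call, among them Cenpe, Dhcr7, Inha, Ldha, Mcam and S100a4, then Rps24 and Rps27 at -0.06 and -0.202, and Rps15, which turned to -0.124. With the lincRNA share as covariate 5629 genes were called, and with both lincRNA-rich libraries left out 3559, where Dsp, Foxm1, Ifit3, Mcam and Rps27 lost their calls. Deviations of same-numbered libraries correlated at -0.465, 0.054 and 0.402, and MOSE-NEO 1 correlated best with MOSE-PAX8 2 (0.627), so pairing by replicate number was not apparent. Deviations from a mean of 3 libraries are tied to each other, so these values cannot exclude such pairing. With the replicate number as a block 3933 genes were called, 3776 of them shared, and Ifit3 and Rps15 lost their calls. Scaling moved the share of higher calls from 52.6% (TMM) to 51% (RLE) and 56.3% (upper quartile). The direction of the set test turned for some lists, none of them called where it turned; their list medians follow, and the cause was not tested. Fry turned extracellular matrix (-0.146), hypoxia (0.274), unfolded protein (-0.015) and granulosa (-0.288). Limma-voom turned hypoxia (0.28) and stromal markers (2.081), and upper-quartile factors ribosomal proteins (0.026). No low-count filter turned extracellular matrix (0.082), ribosomal proteins (0.001) and granulosa (0.439), and the filter of 1 CPM granulosa (-0.291). The block turned hypoxia (0.275), unfolded protein (-0.01) and ribosomal proteins (0.005). Without the 5 chromosomes extracellular matrix (-0.132), ribosomal proteins (-0.021) and granulosa (-0.274) turned, and with the local median removed unfolded protein (-0.065), ribosomal proteins (-0.061) and granulosa (-0.172). The lincRNA covariate turned extracellular matrix (-0.116), hypoxia (0.3), unfolded protein (0.007) and ribosomal proteins (0.02), and leaving out both lincRNA-rich libraries unfolded protein (0.082) and ribosomal proteins (-0.006). Over single libraries left out, the ranges were -0.188 to -0.079 for extracellular matrix, 0.186 to 0.313 for hypoxia, -0.091 to 0.099 for unfolded protein, -0.03 to 0.064 for ribosomal proteins, -0.302 to -0.23 for granulosa, 0.23 to 2.333 for stromal markers and -0.495 to 0.085 for Esam. The stromal range includes settings in which further members of that list passed the low-count filter. Depth leaves genes with about 3 counts per library, near 0.1 CPM, at the floor of these data.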

Other observations

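The genes and families described first, and the tests below of GC content and length, of Y-linked genes, of X-linked genes, of Trp53 and with the local chromosome median removed, were chosen only after the result they concern was seen. The type IV collagen genes Col4a3 and Col4a4, neighbours on chromosome 1 whose products belong to specialised basement membranes such as that of the kidney glomerulus, rose 30.7-fold and 897-fold, to 56.1 ± 7.35 and 594 ± 39.3 CPM (SD, n = 3). Of the other type IV collagen genes, Col4a1 rose 1.36-fold, Col4a6 fell by 0.28 on the log2 scale, and Col4a2 and Col4a5 did not pass, with log2 fold changes of 0.21 and -0.15. The tight junction gene Cldn1 rose from 0.0506 to 35.5 CPM, Myc 3.39-fold, and Mecom and L1cam had 0 counts in MOSE-NEO and 3.55 and 2.92 CPM in MOSE-PAX8. In all, 27 genes had 0 counts in MOSE-NEO and at least 1 CPM in MOSE-PAX8, and 1 gene, Pnma2 on chromosome 14, the reverse. The H2-DM genes, 3 neighbours on chromosome 17 that load MHC class II, all fell, with a median log2 fold change of -2.38.

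The protocadherin clusters on chromosome 18, which encode cell surface recognition proteins, moved apart. Of 20 tested genes of the beta cluster 11 fell and 4 rose, and of 16 of the gamma cluster 10 rose and 0 fell; gamma genes share exons and beta genes are near copies, so reads can be split between them. Among 28 Hox genes 7 fell and 1, Hoxa7, rose. The fall of Fam208a was larger than that of its neighbours on chromosome 14: Ccdc66, which overlaps it, had a log2 fold change of -0.33 and Appl1 of -0.36, while Arhgef3 and Erc2 fell by 2.4 and 1.68 on the log2 scale and Il17rd (0.29) did not pass. Of other genes linked to HUSH, Trim28, Setdb1 and Mphosph8 had log2 fold changes of 0.74, -0.46 and -0.36, about those of their surroundings (local medians 0.752, -0.538 and -0.386), Pphln1 rose by 0.27 ± 0.08 (SE, local median -0.04) and Morc2a (0.02 ± 0.1) did not pass. Called ribosomal protein genes lie in shifted regions, such as Rps15 where the local median was 0.38, Rps24 at -0.39 and Rps27 at -0.56.

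With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one also mixes both lines in each group, so the difference between the lines adds to the spread within groups. Such splits call few genes for that reason alone, and the contrast in called genes decides nothing. The real split gave 4178 called genes, 1135 at least 2-fold and 8 lists, and the highest of the other splits gave 0, 0 and 6. In each case 1 of the 10 splits, the real one, reached the count. Camera at the preset correlation still called between 1 and 6 lists in each of the other splits, with 0 genes called. A list call at this setting can therefore arise without any called gene, which limits the 8 list calls.

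Whole chromosomes and long segments shifted together in MOSE-PAX8, with chromosome 14 lowest among whole-chromosome medians (-0.432). Genes on other autosomes matched to its 393 genes in GC content and transcript length had a median of 0.015 (bootstrap interval -0.001 to 0.032), and none of 1000 shuffles of genes over positions gave a chromosome median as far from 0 (permutation p = 0.001, the smallest they can give), which argues against a bias of either kind and against chance placement. Chromosome 14 genes of low, middle and high expression had medians of -0.384, -0.416 and -0.46, so the shift was present at each level. This is consistent with a difference in chromosome copy number between the lines, as a hypothesis, since no DNA was analysed here. Whether it arose before or after PAX8 was introduced is open.

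Xist RNA was abundant in MOSE-PAX8, at 315, 893 and 397 CPM, and at most 0.0953 CPM in MOSE-NEO. Male cells in MOSE-NEO are argued against by 1 count over 4 Y-linked genes in its 3 libraries, and Xist acting on a single active X by a median of 0.002 for the 368 other X-linked genes (bootstrap interval -0.037 to 0.041). The 6 genes set for the test of escape from X inactivation, such as Kdm6a (2.04-fold) and Kdm5c (1.53-fold), all rose, with a median of 0.88 against random X-linked genes (one-sided permutation p = 0.0014). Of 5 further genes reported to escape in some tissues, 2 rose (Utp14a and Shroom4), 1 fell (Mid1) and 2 did not pass (Usp9x and Bgn). A second, silenced X chromosome in MOSE-PAX8, lost from MOSE-NEO, may therefore explain the difference, as a hypothesis found and tested on the same data.

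Chromosome shifts at the positions of the p53 targets themselves do not account for their lower level. The list median was -0.455 after the local chromosome median was removed. The list then stayed called at the preset correlation (camera adjusted p = 1.94e-07). This removal does not reach effects that shifted genes may have on targets elsewhere, which were not tested. Without that removal the call ended with an estimated correlation (adjusted p = 0.314, range over all alternatives 1.94e-07 to 0.314), which was not run together with it. A lower level of Trp53 transcript is argued against by its log2 fold change of 0.17 ± 0.08 (SE). An effect of PAX8 and a difference between the 2 lines that arose apart from PAX8 cannot be told apart, because the labels name 1 cell line per group. The same limit holds for every difference reported between the lines, and p53 protein and its activity were not analysed here.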
